A study of Mus musculus with 6 samples.

How the data were processed

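RNA was measured in whole kidneys of 3 C57BL/6 (B6) mice and 3 BALB/c mice, 1 library per mouse per the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a Lexogen QuantSeq kit, which primes on poly(A) tails and so reads mainly the 3′ ends of transcripts. Reads therefore report the amount of a transcript's 3′ end, and differences elsewhere in a transcript, such as deletions of inner exons, are not seen.

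Per the submitters' processing notes, Bowtie2 and bedtools were used with the mouse build mm10; their versions, the gene annotation, the handling of reads with several alignments and the use of strand are not given in the sources used here. The deposited values are on a log2 scale, 1 value per gene symbol and library, with 23282 rows and 3 decimals. The unit was worked out from the values: raised from the log2 scale and lowered by 1, the values of each library summed to between 980188 and 1043599, close to the total of CPM values, read counts scaled to a common library total. In every library 100% of the values of up to 20 reads were whole multiples of 1 step within 0.1 read. The deposited log2 values are therefore log2(CPM + 1), with a further scaling factor for each library that sets their sums apart. A read was worth between 0.0968 and 0.118 CPM. Read numbers recovered in this way came to between 8310798 and 10416332 per library. The 35 symbols that appear on several rows (79 rows) were kept as separate rows. No source says whether strand was used in counting. Xist and its antisense partner Tsix, whose exons overlap, had 1126 and 1012 reads in B6 replicate 1, so genes with overlapping exons are named as such where they are reported.

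The design fixed before the data were examined assumed raw counts and named limma on log2(value + 1) as the test for normalized values. The files hold such values, so that test was used. Genes were kept when the deposited log2 value was at least 1 in at least 3 libraries, which left 13317 genes. limma 3.58.1 in R 4.3.3 was fitted to the deposited values with strain as the sole term and with the variance prior following the expression level; tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. With 4 residual degrees of freedom, the prior contributed 18.4. Fold changes are BALB/c over B6 on the log2(CPM + 1) scale, which understates the change of genes at low levels. Means ± SD are in CPM over the 3 libraries of a strain. The labels describe separate mice, so p-values refer to differences between mice. Their variance rests more on the prior, taken from genes of similar level, than on each gene's own spread between mice. Pairs of libraries of the same strain differed by more than sampling noise (chi-square per degree of freedom between 7.93 and 17.1), which argues against the same library having been sequenced again but does not show that libraries came from separate mice.

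Of 35 gene lists fixed beforehand, 30 had at least 5 tested members and were compared with all other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. The camera test was repeated with a correlation estimated from the data. In addition fry was run, which tests whether a list's genes move, on balance, 1 way, and does not compare the list with other genes. Members were also counted after adjustment over the list alone. The genes named below follow a rule fixed beforehand. They are the 10 highest and 10 lowest folds among called genes with a mean of at least 10 CPM and no overlap between the strains; the 5 most abundant called genes in each direction; up to 4 members of each list with the smallest p; and a fixed set of genes of IL-2 signalling, innate lymphoid cells, sex and known strain variants. Some genes that this rule names are not reported here. Other genes are said to have been chosen after their values were seen. The test was tried on simulated reads with the real means and library sizes at a dispersion of 0.05: 46.4% of 97 genes changed by 1 on the log2 scale and 99.0% of 99 genes changed by 2 were recovered, and 4.67% of the 150 calls were unchanged genes. In the same simulation camera called 0 of 20 random lists. Genes were simulated independently of each other, so this cannot show how often correlated genes lead camera to call a list. All genes were given the same dispersion, set by hand and not estimated from the libraries. The simulation therefore cannot show the share of unchanged genes among the calls in the real data.

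Coordinates, strand and exon overlaps came from GENCODE M21 on GRCm38, the assembly that mm10 names, and 22779 rows (97.8%) were placed on it. As a measure of near-identical copies, words of 50 bases were taken every 5 bases from the last 300 bases of a single transcript per gene. This was the longest transcript of the gene's own type, or of any type where there was none. The share of words found without mismatch in another gene was recorded, and other 3′ ends of a gene were not examined. Tables were joined with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1) and plots were drawn with matplotlib 3.10.9.

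Alternatives fixed beforehand were median-of-ratios scaling, total reads with no composition factor, upper quartile scaling, a filter of a read in any library, a mean of at least 5 CPM, limma-voom on the recovered reads, robust variances, the replicate number as a block and leaving out each library in turn. Alternatives added later were a pseudocount smaller than 1 read, a pseudocount of 5 CPM, a variance prior with no trend, genes with no exon overlap and no shared 3′ end, and totals without the 45S ribosomal RNA row. Mitochondrially encoded genes, immunoglobulin and T-cell receptor constant regions, H2-Ea, H60a and Ly6g were not analysed here. Intervals and floors that rest on reads cover counting error only, since the reads carry no molecular identifiers that were used here.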

Results

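Gene expression was measured in whole kidney of C57BL/6 (B6) and BALB/c mice, inbred laboratory strains, with 3 mice per strain. The series concerns strain differences of innate lymphoid cells (ILCs), tissue-resident lymphocytes without antigen receptors, in the kidney and the part of IL-2 signalling and bone marrow progenitors in them. The kidney libraries address which transcripts of the whole organ differ between the strains. The 3 B6 libraries held 9046833, 9765921 and 9308216 reads and the 3 BALB/c libraries 10416332, 8310798 and 9834708. The 45S ribosomal RNA row took 13.9% ± 1.51 of the reads in B6 and 14.5% ± 0.980 in BALB/c (SD, n = 3 each). Values are CPM, and folds are BALB/c over B6 on the log2(CPM + 1) scale.

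The strains differed in 1211 of 13317 genes tested, of which 555 were higher and 656 lower in BALB/c (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was found in 432 of them. Both strains were processed with mm10, the B6 reference, and whether BALB/c reads were lost against it was not tested over these genes. A lower value in BALB/c may therefore not be lower expression. The first principal component held 45.2% of the variance and separated the strains, with B6 libraries between -29.43 and -26.17 and BALB/c libraries between 25.81 and 29.08. The CPM values of the strains did not overlap in 3383 genes (25.4%, where chance gives 10%), among them 1177 of the called genes. Leaving out B6 replicate 1 gave 806 calls and leaving out BALB/c replicate 1 gave 797. A variance prior with no trend, chosen after seeing the data, gave 493 calls, and of the 107 called genes named by the fixed rule 51 lost their call under it. The paragraphs below do not mark these 51 genes, so a gene given there with no lost call may be among them.

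**Figure D1:**
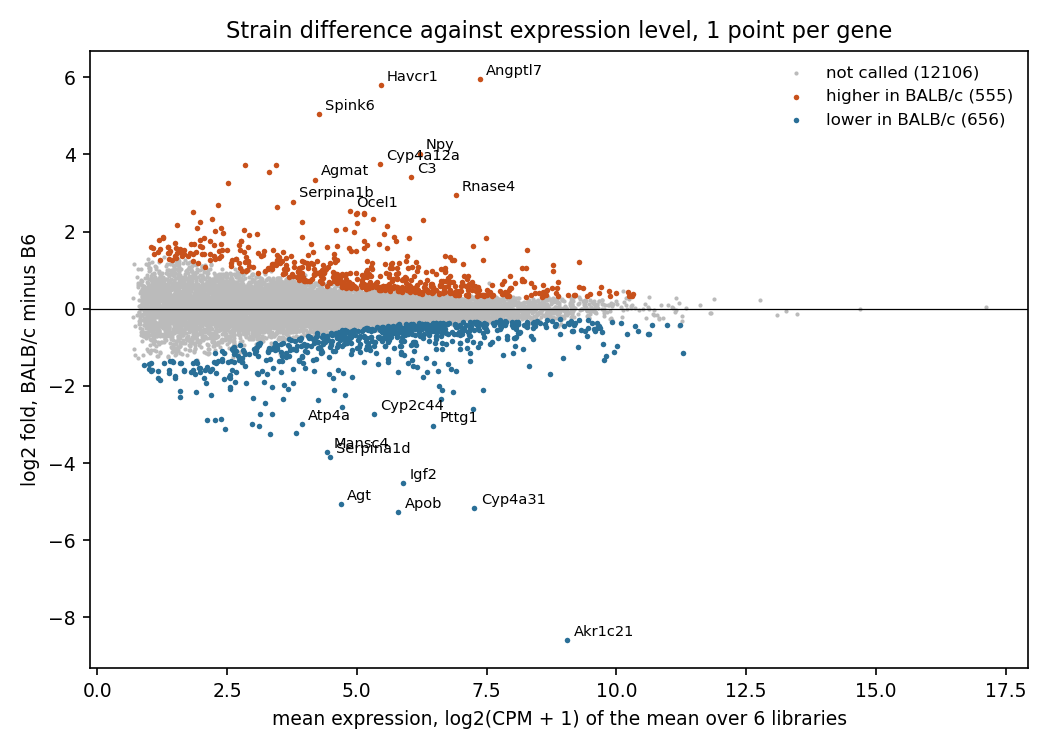
Log2 fold of BALB/c over B6 (vertical axis) against mean expression as log2(CPM + 1) (horizontal axis), with 1 point per gene tested. Coloured points are the 555 genes higher and the 656 genes lower in BALB/c, and Akr1c21 lies lowest at -8.58.

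Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460, GRCm38), rose from 4.26 ± 0.818 CPM in B6 to 324.9 ± 26.0 CPM in BALB/c (SD, n = 3), a log2 fold of 5.96 ± 0.15 (SE, limma adjusted p = 2.67e-18). Havcr1, which encodes the tubular injury marker KIM-1 (chromosome 11, 46735080 to 46779578), rose from 0.545 ± 0.211 to 85.3 ± 18.7 CPM, a log2 fold of 5.79 ± 0.25 (limma adjusted p = 8.16e-14). Spink6, a protease inhibitor, had a log2 fold of 5.04, the neuropeptide gene Npy 4.02, and complement component C3, which went from 10.3 ± 2.55 to 120.0 ± 30.5 CPM, had 3.42. Agmat, named for agmatinase, rose by 3.35. Cyp4a12a, a fatty acid hydroxylase, rose by 3.76, but 51.0% of its 3′ end words occur in another gene. Serpina1b rose by 2.78 with 39.2% of its words shared. Rnase4 (2.95) and Ocel1 (2.53) have exons that overlap those of Ang and Nr2f6, so their reads cannot be assigned to 1 gene with certainty.

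The lowest fold was that of Akr1c21, an aldo-keto reductase gene (chromosome 13, 4574075 to 4586541), which went from 1059.7 ± 144.6 CPM in B6 to 1.89 ± 1.14 CPM in BALB/c (SD, n = 3), a log2 fold of -8.58 ± 0.19 (SE, limma adjusted p = 2.11e-19). Apob, the apolipoprotein of lipoprotein particles (chromosome 12, 7977648 to 8016835), went from 107.7 ± 16.0 to 1.85 ± 0.753 CPM, a log2 fold of -5.27 ± 0.22 (limma adjusted p = 5.77e-14). Cyp4a31, a cytochrome P450 gene, had a log2 fold of -5.17, and Agt, which encodes angiotensinogen, the precursor of angiotensin, had -5.06 with 49.1 ± 9.58 CPM in B6 and 0.503 ± 0.313 CPM in BALB/c. Mansc4 had -3.72, the securin gene Pttg1 -3.05, the proton pump gene Atp4a -2.99 and the cytochrome P450 gene Cyp2c44 -2.74. Igf2, a growth factor gene, had -4.51, its exons overlap those of Igf2os and its 3′ end words are all shared. Serpina1d had -3.85, with 45.1% of its 3′ end words shared, while its relative Serpina1b went the other way. Each of these 20 genes kept its call under all alternatives in which it was tested. They were chosen for extreme folds with no overlap between the strains, so this was likely in advance. Cyp4a12a, Rnase4, Serpina1b, Ocel1, Igf2 and Serpina1d were not tested among genes with no exon overlap and no shared 3′ end.

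**Figure D2:**
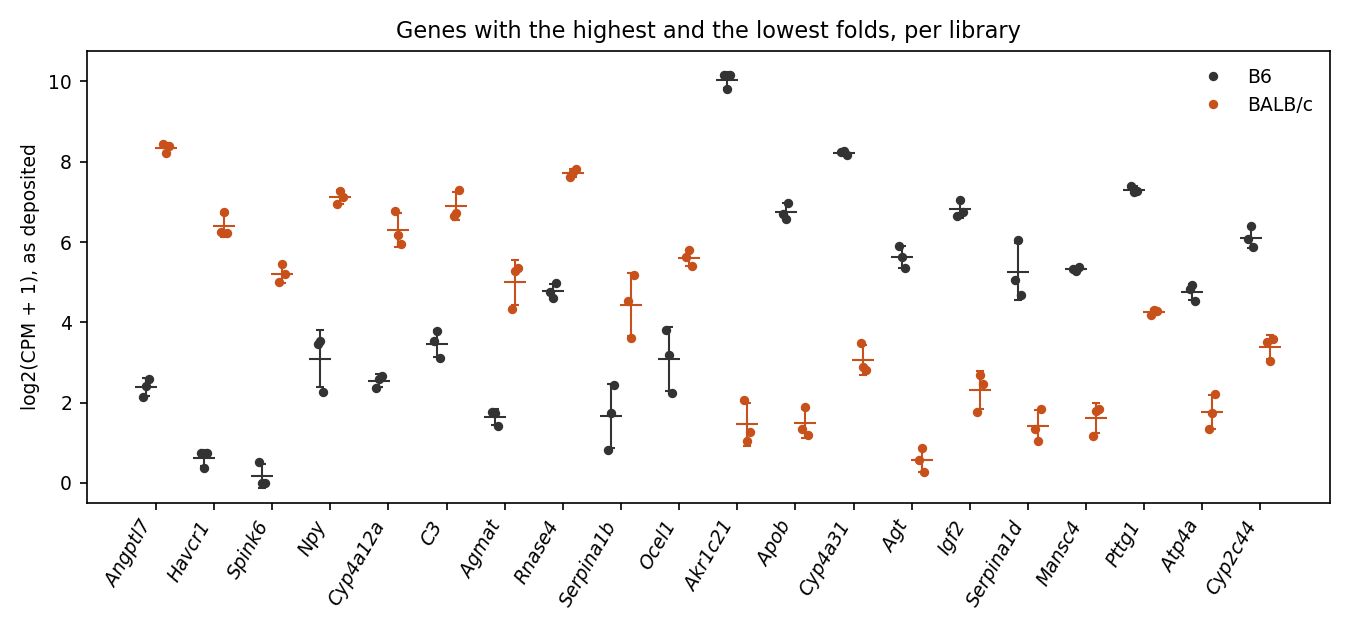
Deposited log2(CPM + 1) values of each library for the 10 highest and 10 lowest folds under the fixed rule. The rule passed over 1 gene model with only a systematic name among the lowest folds. Points are libraries (3 per strain), horizontal marks are means and bars are SD, and the points of the strains do not overlap for any of the 20 genes.

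The most abundant genes that differed moved by less. Among the higher ones, Tmem27, Rpl22, Tmsb4x, Atp5j2 and Camk2n1 had log2 folds of 0.39, 0.33, 0.34, 0.44 and 0.40, and Atp5j2 shares 11.8% of its 3′ end words. Tmem27, which encodes collectrin, went from 1110.1 ± 170.9 to 1441.5 ± 16.2 CPM (SD, n = 3). Among the lower ones, Chchd2, which encodes a mitochondrial protein and shares 23.5% of its 3′ end words, went from 3454 ± 425.4 to 1557.7 ± 76.6 CPM, a log2 fold of -1.14 ± 0.10 (SE, limma adjusted p = 1.69e-08). The calcium-binding protein gene S100g had -0.43, Hsp90ab1 -0.41, Actb -0.41 and the beta-globin gene Hbb-bs -0.65. Leaving out BALB/c replicate 1 ended the calls of Tmem27, Rpl22, Tmsb4x (limma adjusted p = 0.0870), Atp5j2 (0.0542), Camk2n1, S100g and Actb (0.0818). Leaving out B6 replicate 1 ended those of Tmem27, Rpl22, Camk2n1, S100g and Hbb-bs (0.0513), and over all left-out libraries the highest adjusted p was 0.0729 for Tmem27, 0.138 for Rpl22, 0.0811 for Camk2n1 and 0.253 for S100g. S100g also lost its call with total-read and upper quartile scaling.

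Among the IL-2 pathway and ILC genes fixed beforehand, Il2, Il2ra, Il7r, Il1rl1, Il2rb and Il7 had at most 20 reads in a library. Il2 had 1 read in B6 and 3 reads in BALB/c over all libraries of a strain, Il2ra had 10 and 1, Il7r had 12 and 10, and Il1rl1, the receptor of IL-33, had 10 and 30. These genes lay below the filter and were not tested. Il2rb, the IL-2 receptor beta chain, had 10 reads in B6 and 48 in BALB/c, with a log2 fold of 1.003 ± 0.417 (SE, n = 3, limma adjusted p = 0.152). The common gamma chain gene Il2rg had a log2 fold of -0.31 (limma adjusted p = 0.716), Il7 0.09 (0.940), Il33 -0.51 (0.301), Stat5a 0.17 (0.801) and Stat5b -0.01 (0.974). Exons of Stat5a overlap those of Stat3, and exons of Gata3 those of 9230102O04Rik. Gata3, a transcription factor of ILC2s that kidney epithelium and mesangium also express, had -0.58 (0.0794), and Rora had 0.05 (0.874). None of these passed the test, and intervals of Il2rb and Il7 are wide because each rests on at most 20 reads in a library.

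Of 9 tested members of the ILC lineage list, 1 rose, Zbtb16, which encodes the transcription factor PLZF, by 1.75 ± 0.37 (SE, limma adjusted p = 0.00303). Zbtb16 was low in both strains, at 1.06 ± 0.534 CPM in B6 and 5.97 ± 2.03 CPM in BALB/c (SD, n = 3). Which cells of the kidney expressed it was not tested. Adjusted over the list alone, 4 members were called, 2 in each direction. Of 15 members of the IL-2 and common gamma chain list, 1 rose, the kinase gene Jak3 (1.25, limma adjusted p = 0.0303), whose exons overlap those of Insl3 and whose 3′ end words are all shared, and 1 was called when adjusted over the list alone. Leaving out any of 5 of the libraries (all but B6 replicate 2) ended the Jak3 call, with an adjusted p of up to 0.132. Of 10 members of the ILC niche and alarmin list, 1 fell, the chemokine gene Ccl28 (-2.73, limma adjusted p = 5.69e-04), also 1 when adjusted over the list alone, and limma-voom on the recovered reads and robust variances each ended that call. As lists, none of these 3 differed from other genes (camera adjusted p = 0.811, 0.406 and 0.633).

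**Figure D3:**
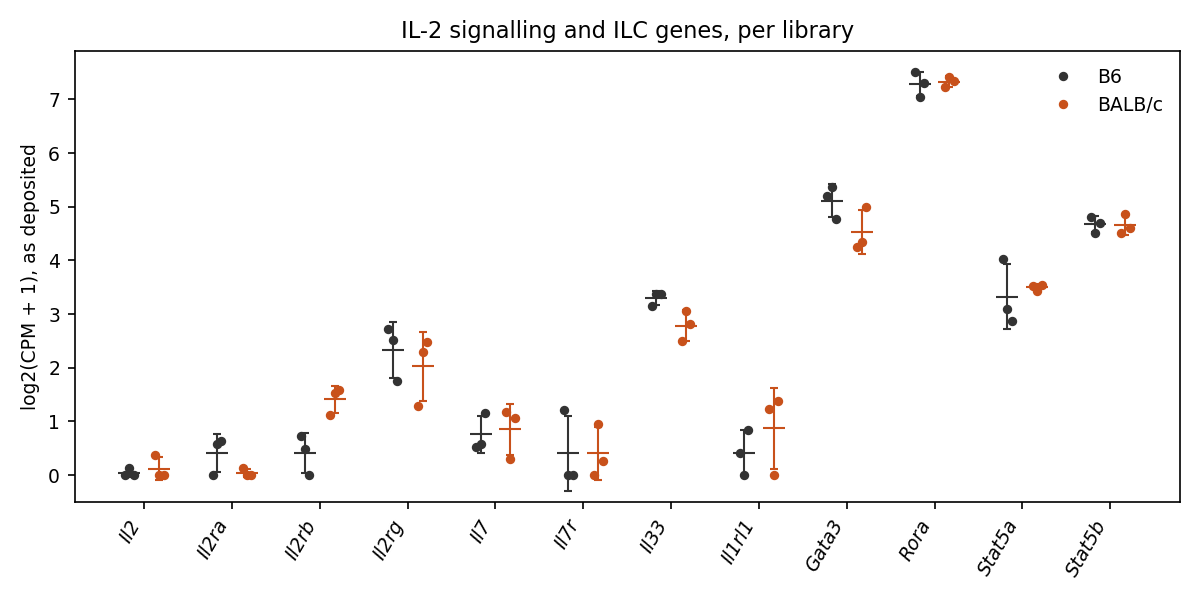
Deposited log2(CPM + 1) values of each library for the genes of IL-2 signalling and ILCs fixed beforehand. Points are libraries (3 per strain), horizontal marks are means and bars are SD, and none of the 8 genes that were tested passed the test.

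Markers of other immune cells moved in both directions. Of 18 macrophage and myeloid members, 3 rose and 0 fell, and 7 were called when adjusted over the list alone, 3 higher and 4 lower. Csf1r, the receptor of macrophage colony-stimulating factor, rose from 63.0 ± 10.1 to 118.1 ± 14.96 CPM (SD, n = 3), a log2 fold of 0.90 ± 0.13 (SE, limma adjusted p = 4.28e-05). Its exons overlap those of Hmgxb3. Cx3cr1 rose by 0.88 and the lysozyme gene Lyz2, with 21.6% of its 3′ end words shared, by 1.22, and each lost its call when 1 of 4 libraries was left out. Those libraries were B6 replicates 1 and 3 and BALB/c replicates 1 and 3 for Cx3cr1 (limma adjusted p up to 0.176), and B6 replicates 2 and 3 and BALB/c replicates 1 and 2 for Lyz2 (up to 0.200). Ms4a7 had -1.25 (limma adjusted p = 0.0746). Of 8 T and NK cell members, 1 fell, Cd8a (-1.40, limma adjusted p = 0.0279), also 1 when adjusted over the list alone, and its call ended without B6 replicate 1 or 3 or without BALB/c replicate 1 or 2 (up to 0.146). Of 5 dendritic cell members 0 were called by limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. Camera called none of these lists (adjusted p = 0.919, 0.948 and 0.676). The neutrophil list had 2 tested members, of which S100a9 rose by 1.62 (limma adjusted p = 0.00517) and S100a8 had 1.19 (0.0820). With no filter beyond 1 read the list had 7 members, and camera called it higher (adjusted p = 0.0220). The B and plasma cell list had 2, Jchain at -0.17 (0.846) and Blnk at 0.06 (0.912).

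The strains carry different haplotypes of the MHC, the region that holds most genes of antigen presentation named here. Whether BALB/c reads of this region were lost against the B6 reference, or assigned to another gene, was not tested. Folds of these genes may therefore not be changes in expression. Of 15 members of the MHC class I list, 1 rose and 2 fell, and 6 were called when adjusted over the list alone, 2 higher and 4 lower. H2-K1 went from 180.4 ± 2.96 to 58.3 ± 6.30 CPM (SD, n = 3), a log2 fold of -1.62 ± 0.11 (SE, limma adjusted p = 4.00e-10), and H2-D1 from 195.8 ± 17.6 to 412.2 ± 73.7 CPM, a log2 fold of 1.06 ± 0.11 (limma adjusted p = 4.40e-07), with 17.6% of its 3′ end words shared. B2m had -0.37, a call that ended without B6 replicate 3 or BALB/c replicate 2 or 3 (limma adjusted p up to 0.199) and with upper quartile scaling. Camera did not call this list (adjusted p = 0.578). Of 7 members of the MHC class II list, 3 rose and 0 fell, and 4 rose when adjusted over the list alone. One riser was H2-Ea-ps (2.18), used below as a check of the labels, with 0 reads in the B6 libraries. Of the 7 folds 5 were positive, while H2-Ab1 and H2-DMb1 had -0.29 and -0.15 and were not called. H2-Aa rose by 0.47 and H2-Eb1 by 0.47. Without BALB/c replicate 1 both lost their calls (limma adjusted p = 0.0659 for H2-Aa and up to 0.208 for H2-Eb1, which also lost it without B6 replicate 1 or BALB/c replicate 2). Camera called the list higher (adjusted p = 0.0400, adjusted p = 0.650 with an estimated correlation). It lost that call without B6 replicate 1 or 2 or BALB/c replicate 1 or 2 (adjusted p up to 0.192), with a mean of at least 5 CPM (0.197), with no filter beyond 1 read (0.137) and with no trend in the variance prior (0.143).

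Of 24 interferon-stimulated genes, 2 rose and 2 fell, the same numbers as adjusted over the list alone. Stat2 rose by 1.38 and Gbp3, a guanylate-binding protein gene, by 0.81, whereas Ifit3 had -1.03 and Rsad2, which encodes viperin, had -0.72 (limma adjusted p = 0.00153, 0.00222, 2.58e-04 and 2.73e-04). Of 17 complement and chemokine genes, 2 rose and 1 fell, against 2 and 2 when adjusted over the list alone. Besides C3, C4b rose by 1.42 with 52.9% of its 3′ end words shared, and its call ended without BALB/c replicate 2 or 3 (limma adjusted p up to 0.0634). The chemokine gene Cxcl14 had -1.11 (limma adjusted p = 3.52e-04). Camera called neither list (adjusted p = 0.919 and 0.633).

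Called genes of the proximal tubule, the loop of Henle and the distal tubule lay in both directions. Of 24 proximal tubule genes, 2 rose and 5 fell, and 9 were called when adjusted over the list alone, 2 higher and 7 lower. The lactate transporter gene Slc5a12 rose from 374.0 ± 69.4 to 863.2 ± 17.3 CPM (SD, n = 3), a log2 fold of 1.22 ± 0.11 (SE, limma adjusted p = 2.39e-08), and the amino acid transporter gene Slc7a9 rose by 0.60. The bicarbonate transporter gene Slc4a4 had -0.64 and Pck1, a gluconeogenic enzyme gene, had -0.57. Of 11 loop of Henle genes, 2 rose and 1 fell, against 2 and 3 when adjusted over the list alone. Bst1 rose by 1.51, with exons that overlap those of Fbxl5, and Egf, with exons that overlap those of 6330410L21Rik, had -0.38. Cldn10 rose by 0.36, a call that ended without B6 replicate 2 or 3 or BALB/c replicate 1 or 2 (limma adjusted p up to 0.101). Of 9 distal tubule genes, 1 rose and 4 fell, against 2 and 5 when adjusted over the list alone. The parvalbumin gene Pvalb rose from 66.5 ± 8.49 to 161.2 ± 13.9 CPM, by 1.27 ± 0.12 (limma adjusted p = 4.76e-08), while the sodium-calcium exchanger gene Slc8a1 had -0.62, the thiazide-sensitive cotransporter gene Slc12a3 had -0.53 and Calb1 had -0.48. Of 18 collecting duct genes, 1 rose, Aqp6 by 0.54, also 1 when adjusted over the list alone, and its call ended without B6 replicate 1 or 3 or BALB/c replicate 2 or 3 (up to 0.0758). Camera called none of these lists (adjusted p = 0.208, 0.633, 0.140 and 0.242), but called the proximal tubule list lower without BALB/c replicate 3 (0.0499).

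Podocyte genes, expressed in the filtering cells of the glomerulus, moved in both directions. Of 10 podocyte genes, 2 rose and 2 fell, against 4 and 2 when adjusted over the list alone. Nphs1, which encodes nephrin, overlaps Nphs1os and shares 21.6% of its 3′ end words, went from 13.1 ± 0.346 to 0.834 ± 0.523 CPM (SD, n = 3), a log2 fold of -2.98 ± 0.33 (SE, limma adjusted p = 1.11e-06), and the phosphatase gene Ptpro had -1.69. Cdkn1c rose by 0.47, a call that ended without BALB/c replicate 2 (limma adjusted p = 0.0732). Of 14 endothelial genes 0 were called by limma, 4 had an unadjusted p under 0.05 and 2 were lower when adjusted over the list alone. Of 17 fibroblast, mesangial and smooth muscle genes, 1 rose and 2 fell, against 1 and 6 when adjusted over the list alone. The smooth muscle actin gene Acta2 had -0.82 (limma adjusted p = 1.66e-04) and the integrin gene Itga8, which overlaps E030013I19Rik, rose by 1.25. The collagen gene Col1a2 had -0.50, a call that ended without BALB/c replicate 1 (0.0608). Camera called this last list lower (adjusted p = 0.0487, adjusted p = 0.650 with an estimated correlation), and the call ended without B6 replicate 2 or 3 or BALB/c replicate 1 or 3 (up to 0.206), with a mean of at least 5 CPM (0.128), a pseudocount of 5 CPM (0.0585) or no trend (0.119). It did not call the podocyte and endothelial lists (adjusted p = 0.310 and 0.220), but called the podocyte list higher among genes with no exon overlap and no shared 3′ end (0.0405).

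Of 15 tested kidney injury genes, 2 rose and 3 fell, against 2 and 4 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.633). Beside Havcr1, Cdkn1a, a cell cycle inhibitor gene, rose from 12.6 ± 2.11 to 32.5 ± 1.56 CPM (SD, n = 3), a log2 fold of 1.31 ± 0.19 (SE, limma adjusted p = 4.66e-05). The fibrinogen gene Fgb had -3.24 and the clusterin gene Clu had -0.75 (limma adjusted p = 2.24e-06 and 1.02e-05).

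Genes of detoxification and sterol synthesis were mostly lower where they were called. Of 20 genes of the glutathione and NRF2 target list, 1 rose and 6 fell, and 1 rose and 8 fell when adjusted over the list alone. The glucuronosyltransferase gene Ugt2b38 had -2.55 ± 0.28 (SE, n = 3, limma adjusted p = 7.30e-07), the glutathione transferase gene Gsta4 -0.85, and the carboxylesterase genes Ces1d and Ces1f -0.62 and -0.97. Camera called the list lower (adjusted p = 4.59e-04, adjusted p = 0.275 with an estimated correlation). In fry, which asks whether the list's genes move 1 way and does not compare them with other genes, the directional adjusted p was 0.00294. None of the other lists that camera called passed this fry test. Their directional fry adjusted p lay between 0.134 (cholesterol synthesis, female-biased) and 0.294 (red blood cell, immediate early and heat shock). Of 20 cholesterol synthesis genes, 0 rose and 5 fell by limma, and 8 fell when adjusted over the list alone. The squalene epoxidase gene Sqle had -1.18 ± 0.17 (limma adjusted p = 3.35e-05) and the sterol oxidase gene Msmo1 -0.83. Hmgcs1 had -0.38 and Mvd -0.48. The call of Hmgcs1 ended without B6 replicate 1 or 3 or BALB/c replicate 3 (limma adjusted p up to 0.117), and that of Mvd without B6 replicate 2 or 3 or BALB/c replicate 1 or 2 (up to 0.117). Camera called the list lower (adjusted p = 0.00480, adjusted p = 0.650 with an estimated correlation).

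Of 23 genes of fatty acid oxidation and PPAR alpha targets, 5 rose and 2 fell, against 6 and 3 when adjusted over the list alone. The thioesterase gene Acot2 rose from 172.4 ± 27.2 to 268.6 ± 34.8 CPM (SD, n = 3), a log2 fold of 0.64 ± 0.12 (SE, limma adjusted p = 6.40e-04), and Cyp4a10 rose by 0.54. Of 24 nuclear oxidative phosphorylation genes 0 were called by limma, also adjusted over the list alone, with 5 at an unadjusted p under 0.05. Of 10 renin-angiotensin genes, 1 rose and 2 fell, the same numbers as adjusted over the list alone. Besides Agt, the neprilysin gene Mme rose by 0.61, and the aminopeptidase gene Anpep had -0.39, a call that ended when any library but B6 replicate 3 was left out (limma adjusted p up to 0.112) or with total-read scaling. Camera called none of these 3 lists (adjusted p = 0.141, 0.503 and 0.406), but called the fatty acid list higher among genes with no exon overlap and no shared 3′ end (0.0143) and without BALB/c replicate 3 (0.0316).

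Of 17 immediate early and heat shock genes, 6 rose and 2 fell, against 8 and 3 when adjusted over the list alone. Egr1 rose from 10.8 ± 8.23 to 57.3 ± 27.1 CPM (SD, n = 3), a log2 fold of 2.46 ± 0.34 (SE, limma adjusted p = 2.55e-05), a call that ended with robust variances. Junb rose by 1.57, with exons that overlap those of Prdx2, and Jun by 1.21, whereas Klf4 had -1.58. Camera called the list higher (adjusted p = 0.0253, adjusted p = 0.650 with an estimated correlation), and the call ended without B6 replicate 1 or BALB/c replicate 3 (adjusted p up to 0.159), with a mean of at least 5 CPM (0.128), among genes with no exon overlap and no shared 3′ end (0.114) and with no trend (0.0952). Of 15 circadian clock genes, 2 rose and 3 fell, against 2 and 5 when adjusted over the list alone. The repressor genes Nr1d1, which overlaps Thra, and Nr1d2 rose by 1.48 and 1.42, and Clock had -0.61. Per2 had -1.17, a call that ended when any library but BALB/c replicate 3 was left out (limma adjusted p up to 0.140). Camera did not call the clock list (adjusted p = 0.811). Of 13 cell cycle genes, 1 fell, Mcm6 (-3.04 ± 0.41, limma adjusted p = 1.79e-05), also 1 when adjusted over the list alone (camera adjusted p = 0.310).

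Of 10 red blood cell genes, 0 rose and 2 fell by limma, and 6 fell when adjusted over the list alone. Hbb-bs and Hbb-b1 had -0.65 each, with nearly equal read numbers in each library (19439 and 19251 in B6 replicate 1), and the calls of both ended without B6 replicate 1 (limma adjusted p = 0.0513 and 0.0501). Hbb-bt and Hbb-b2 had -0.44 and -0.43 (limma adjusted p = 0.0669 and 0.0681), also with nearly equal read numbers (5021 and 4803 in B6 replicate 1). The counts and camera treat the rows of each pair as separate genes, so the same reads may enter them more than 1 time. These beta-globin rows were among the strain variants fixed beforehand. Whether their BALB/c reads were lost against the B6 reference was not tested, so their lower values may not be lower expression. BALB/c replicate 3 lay in the B6 range for Hbb-bs, at 10.688 on the log2(CPM + 1) scale against 10.657 in B6 replicate 2. BALB/c replicates 1 and 2 had 10.101 and 9.978. Camera called the red blood cell list lower (adjusted p = 0.00132, adjusted p = 0.650 with an estimated correlation). Of 22 ribosomal protein genes of the fixed list, 2 rose and 2 fell, against 3 and 2 when adjusted over the list alone (camera adjusted p = 0.284, and called higher at 0.0292 without B6 replicate 3). Rps2 and Rpl3 had -1.40 and -1.36, with 78.4% and 76.5% of their 3′ end words shared, and exons of Rps2 overlap those of Snhg9 and Snora64. Rpl5, with exons that overlap those of Fam69a, rose by 0.32 and Rpl7, with 74.5% of its words shared, by 0.36. Both lost their calls without B6 replicate 2 or BALB/c replicate 1 or 2, and Rpl7 also without B6 replicate 1 (limma adjusted p up to 0.104 and 0.160). The fat and adrenal list had 2 tested members, Akr1b7 at 0.57 (0.241) and Star at 0.23 (0.790).

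**Figure D4:**
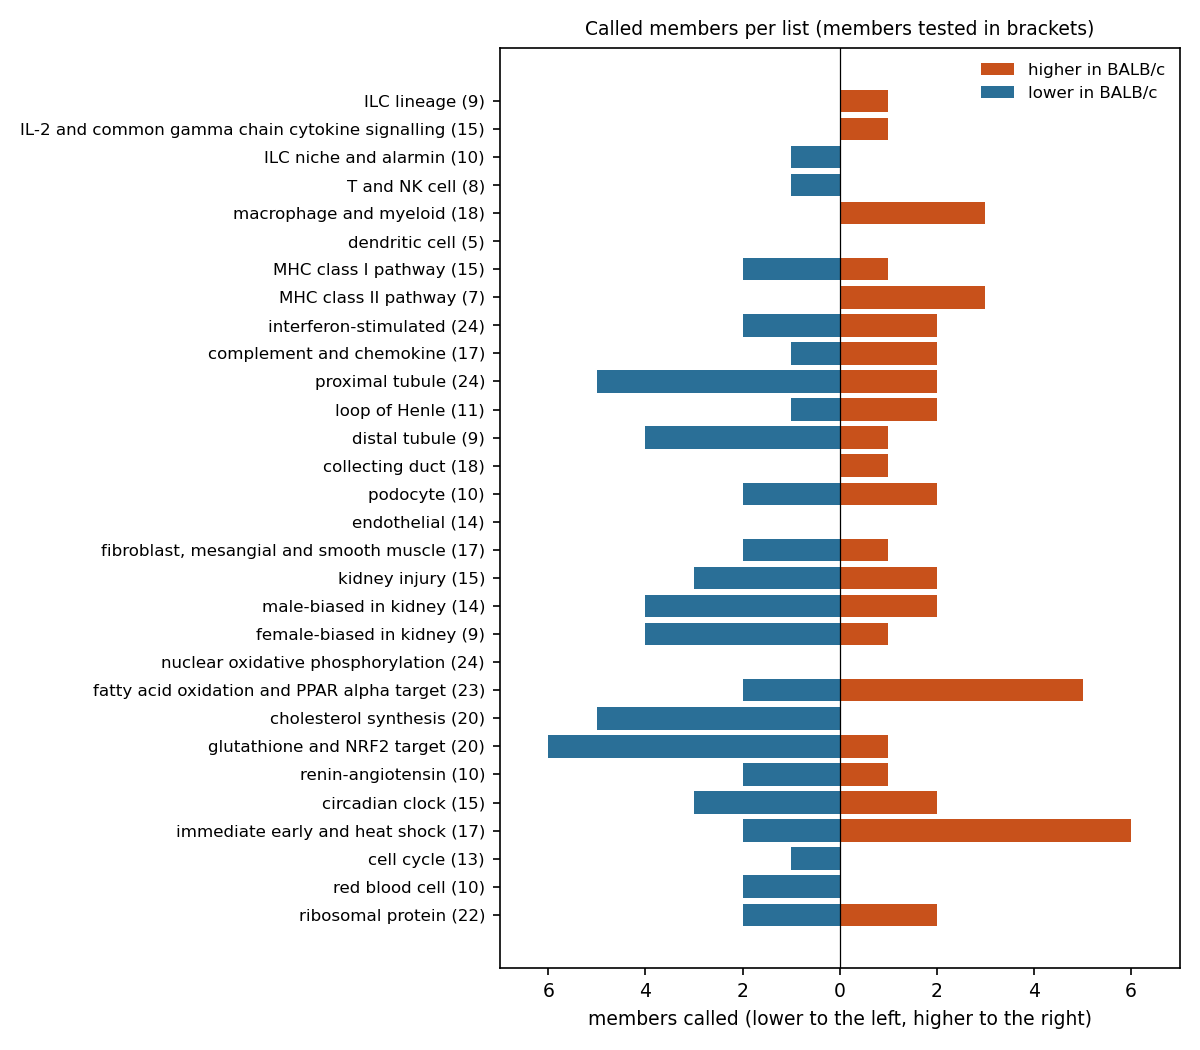
Number of members called lower (left) and higher (right) in BALB/c for each of the 30 lists tested, with the number of members tested in brackets. The glutathione and NRF2 target list had 6 lower members, and the immediate early and heat shock list had 6 higher ones.

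Genes known to differ between male and female mouse kidneys included called members in both directions. Of 9 female-biased genes, 1 rose and 4 fell, against 1 and 5 when adjusted over the list alone. Cyp2a4 had -2.15 ± 0.12 (SE, n = 3, limma adjusted p = 1.01e-11), with 21.6% of its 3′ end words shared. Slc7a12 had -0.40 and Slc22a26 -1.35, and Cyp4a14 rose by 0.38. Their calls ended without BALB/c replicate 1 (limma adjusted p = 0.160 for Cyp4a14), and for Slc7a12 and Slc22a26 also without B6 replicate 1 or 3 or BALB/c replicate 3, and for Slc7a12 without BALB/c replicate 2 (up to 0.211 and 0.173). Camera called the list lower (adjusted p = 0.0370, adjusted p = 0.650 with an estimated correlation), a call that ended without B6 replicate 1 or 3 (up to 0.128), with a mean of at least 5 CPM (0.156), with no filter beyond 1 read (0.0622), with no trend (0.145) and among genes with no exon overlap and no shared 3′ end (0.295). Of 14 male-biased genes, 2 rose and 4 fell, against 2 and 6 when adjusted over the list alone (camera adjusted p = 0.406). Besides Cyp4a12a, Acy3 rose by 0.55, and Hsd3b4, whose 3′ end words are all shared, had -0.49, a call that ended without B6 replicate 1 (0.0501). The median, the mean and the direction of camera's test differed in sign for 6 lists, namely ILC niche, T and NK cell, macrophage and myeloid, loop of Henle, podocyte and circadian clock.

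Genes with known strain or sex differences served as a check of the labels. H2-Ea-ps had 0 reads in the 3 B6 libraries and between 20 and 52 reads in each BALB/c library, at least 35.5-fold higher in BALB/c against a floor of 3 reads over the B6 group (limma adjusted p = 0.00118). Xist, the RNA of the inactive X chromosome in females, had between 1035 and 1963 reads in every library, and its exons overlap those of Tsix. Its log2 fold was 0.56 ± 0.13 (SE, n = 3, limma adjusted p = 0.00444). The Y-linked genes Eif2s3y, Kdm5d and Uty had 0 reads in all 6 libraries, and Ddx3y had at most 8. With the Xist reads in every library, these values argue against a difference in the sex of the mice between the strains. Nnt, which lacks inner exons in some B6 substrains, had a log2 fold of 0.00 (limma adjusted p = 0.994), and a 3′ tag outside the deleted part checks nothing.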

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

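The variance prior with no trend, the pseudocounts smaller than 1 read and of 5 CPM, the set of genes with no exon overlap or shared 3′ end, and totals without the 45S row were chosen after seeing the data (the smaller pseudocount was planned for the lists). The planned DESeq2 test and edgeR were not run; on recovered reads, limma-voom was the test that was run. With no trend, 493 genes were called, 227 higher and 266 lower, of which 443 were among the 1211, and 3 lists; the cause was not tested. A pseudocount of 5 CPM left 186 genes at 2-fold or more instead of 432, since it shrinks the folds of low genes by construction. Lists called by camera fell from 7 to 3 with a mean of at least 5 CPM and to 0 with an estimated correlation (1 list at an unadjusted p under 0.05). The directional test of fry, which asks another question, called 1 list. Leaving out 1 library gave between 797 and 1138 calls, between 350 and 534 higher, between 415 and 604 lower, and between 4 and 7 lists; such fits have fewer mice. The other settings kept each count within 1.5 times. Replicate numbers are shared by the strains but do not pair the mice: same-numbered libraries had correlations of deviations of 0.0115, -0.057 and -0.0844 across genes. With the replicate block 977 genes were called (453 higher, 524 lower), 397 at 2-fold or more, and 7 lists. Over 2917 values of 157 named genes under alternatives, 196 lost a call, 39 gained one and 0 reversed. Of 107 called named genes, 53 kept the call throughout. Il2, Il2ra, Il7r and Il1rl1 fell below the filter and were not tested.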

Other observations

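Tests of ribosomal proteins, Havcr1, clock genes, the direction of neighbouring genes and other splits of the libraries were chosen after the results were seen, and the test of how often called genes are neighbours was fixed before its result was seen. Genes with no read in 1 strain were looked for after the report's comparisons, and the genes named here were chosen after their values were seen. With at least 10 reads in each library of the other strain, 7 genes had 0 reads in all B6 libraries and 10 had 0 reads in all BALB/c libraries. Whether BALB/c reads of the 10 were lost against the B6 reference was not tested, so they may not lack expression. Among the 10, exons of Igf2os overlap those of Igf2, and Marcksl1-ps4 overlaps Akr1c19. C130080G10Rik, with no B6 reads, and Hapln1 and A830052D11Rik, with no BALB/c reads, were not called by limma. Mybpc3, which encodes a myosin-binding protein, had between 79 and 151 reads in the BALB/c libraries, at least 115.3-fold higher than in B6 against a floor of 3 reads over the group. Azgp1, which encodes a secreted glycoprotein, had between 44 and 84 reads in the B6 libraries, at least 63.9-fold lower in BALB/c. Ifi202b, an interferon-inducible gene, was at least 19.3-fold higher in BALB/c, and Cyp2r1, a vitamin D 25-hydroxylase gene, was at least 20.4-fold lower. The neighbours of Akr1c21 were also lower in BALB/c, with log2 folds of -2.25 for Akr1c19, -1.28 for Akr1c18 and -1.30 for Akr1c14 (limma, each called); exons of Akr1c19 overlap those of Marcksl1-ps4.

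Called genes lay next to each other more often than chance gives. Among 9374 tested genes with no exon overlap and no shared 3′ end, 856 were called, and 127 pairs of neighbours were both called, against a mean of 78.1 and a highest value of 113 in 10000 shuffles of the calls (one-sided permutation p = 0.0001, the smallest they can give). Shuffling within 10 classes of expression level, added after that result, gave a mean of 78.5 and the same p. The pairs went the same way in 51.2% of cases (95% exact binomial interval 42.2% to 60.1%; 50.1% in the shuffles), which argues against shared regulation that moves neighbours the same way as the whole cause, since that needs 69.3%. The excess is consistent with a hypothesis of strain haplotype blocks (runs of sequence that differ between the strains), but the files hold no sequence to test it, and regulation that moves neighbours apart, or the same way in some pairs, was not tested.

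The counts of the comparison were set against other splits of the 6 libraries into 3 and 3. The real split called 1211 genes, 555 and 656 in the 2 directions, and 432 at 2-fold or more. The highest of the other splits called 0 for each (limma; at an unadjusted p under 0.05, 2839 genes in the real split and at most 628 in another). For each of these 4 counts 1 of 10 splits, the real one, reached the real value. The 7 lists called by camera were reached by 2 of 10 splits, the highest other split calling 8. With 10 splits a share under 0.05 cannot be had. The other splits mix the strains, which adds the strain difference to their spread.

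A few ribosomal protein genes were far lower in BALB/c while their family was not. Of 84 family members tested by name, 5 were called and lower by 1 or more on the log2 scale (Rpl21 -2.33, Rpl26 -1.69, Rps2, Rpl3 and Rpl29 -1.01), and 0 were called and higher by as much. A lower level of the whole family is argued against by its median of 0.1708 with an interquartile range of 0.186. Loss of BALB/c reads against the B6 reference may be a cause and would lower genes in BALB/c alone, but the result turns on the cutoff, and both cutoffs were set with the values in view: a two-sided exact binomial test gave p = 0.0625 for 5 against 0, and p = 0.03125 for the 6 against 0 that lie 1 or more from the family median, which adds Rps4l. Division of reads between near-identical copies is not decided either, since 4 of the 5 genes and 55 of the other 79 share 3′ end words (Fisher's exact p = 1.0), so these explanations cannot be told apart from a strain difference in expression.

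Havcr1 is a marker of tubular injury, and of the other 14 tested members of the injury list 1 (Cdkn1a) was called higher and 3 were called lower. The mean log2 difference of these 14 members was -0.4329 with a standard error of 0.0659, and their median was -0.18 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The mean is carried by 3 fibrinogen genes: without them, a repeat added after that result, the other 11 averaged 0.02 with a standard error of 0.0744 (two-sided exact permutation p = 0.8), and both means argue against an injury that raises these genes at least 2-fold on average. Reads from an overlapping or near-identical gene are argued against by the annotation, which has no exon overlap and a shared 3′ end percentage of 0.0. That percentage covers the end of a single Havcr1 transcript, and other 3′ ends were not examined. A variant at the gene itself and an injury response of another kind stay open as untested hypotheses.

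Among called clock genes, Nr1d1 and Nr1d2 were higher and Clock, Cry1 and Per2 lower in BALB/c. Genes were divided into 2 phases after their values were seen, which left out Per2 and Cry2, and exons of Nr1d1, Dbp and Cry2 overlap those of other genes. Between 8 genes of 1 phase (such as Nr1d1, Nr1d2 and Dbp) and 5 of the other (such as Arntl, Clock and Cry1), the mean difference changed from -0.53 ± 0.17 in B6 to 0.65 ± 0.22 in BALB/c (SD, n = 3), by 1.1817, and by 0.99 with Per2, which goes the other way, placed among the first in a repeat added after that result (two-sided exact permutation p = 0.1 for both, the smallest that 3 against 3 allows). Collection of the strains at different times of day could give this, and so could a strain difference in the clock. Both follow the strain in this design and cannot be told apart, and no collection time was used here. The rise of Egr1, Jun and Junb could follow collection as well, which was not tested.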
